A study of Mus musculus with 10 samples.

How the data were processed

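RNA-seq of mammary tissue at lactation day 1 was used, with 2 libraries each of WT, line B and line C. The labels' protocol text for the WT libraries describes chromatin immunoprecipitation and that for the lines describes purified poly(A) RNA, so the protocol of the WT RNA libraries is not given in the sources used here. The submitters' processing notes name CASAVA, Bowtie2 and STAR and the build mm9, without versions or roles, and the tool that made the coverage is not given in the sources used here.

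Each deposited file lists intervals with a coverage value. In 3 files (line B replicate 2 and both line C libraries) the deposited values are a signal that is never below 0. In the other 3 the deposited values are a score that falls slightly below 0 after very high peaks, and these negatives were set to 0. From the values, each library was made of reads extended to 1 length, and the authors had scaled the sum of value times length to about the same total in every file, also in files that lack whole chromosomes. The loss therefore preceded the authors' scaling, and deposited values were not compared between libraries except as an alternative. Values smaller than about 0.05 are not listed, so that positions with 1 read are partly missing in WT replicate 2 and line B replicate 1. The depth, 15 to 35.4 M estimated reads (M, 1000000 reads), limits weakly transcribed segments most in line C.

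A stretch was taken as lost where a library listed nothing over more than 3000000 bp that others filled, and its start was moved back over positions at under 0.1% of the highest other library. Segments were positions where the mean of the 6 libraries was 0.5 or more per base, joined over gaps of up to 2000 bp and at least 500 bp long. No annotation of this build was used, so exons could not be summed as had been planned, and ribosomal RNA could not be removed by name. The fallback of transcribed segments had been set before the data were examined. The value of a segment is its signal per kb per 1000000 of segment signal, called scaled signal per kb, divided by a median-of-ratios factor over segments at 1 or more in all 6 libraries. Segments with a mean of 0.5 or more were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(value + 0.25), with all 6 libraries in 1 model and Benjamini-Hochberg adjustment. Fold changes are on the log2(value + 0.25) scale, which understates changes of weak segments. Segments were built with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

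Gene names are provisional. Approximate mm9 positions were recalled from general knowledge for 79 genes of the lists fixed before the data were examined, after signal in the files had been looked at. A name was kept where the strongest segment within 20 kb had 0.85 to 1.15 times the gene's length, plus up to 1600 bp, in a table of assembly GRCm38.p6. This rule replaced a first one after the first one's outcome had been seen. On these positions 38 of 79 passed the final rule, 48.1%, against 4.4% of 790 randomly shifted positions, and 40 passed the first rule, 50.6%, against 9.1%. Genes known to have been recalled while looking at the strongest segments were left out, but this list may be incomplete, so the passing share is in part circular. The first rule had been tried on a wider set of positions, and both shares are for the 79 kept. Only such genes were tried as came to mind, so the lists are covered in part, and a name may be wrong. Stat5b, Stat5a and Stat3 were built from several segments, bounds set after seeing the data, and the table lists them as neighbours in this order. The casein windows on chromosome 5 were set by hand after seeing the data, in the table's order of the casein genes. Also set after seeing the data were the rule for lost stretches, and the levels used for segments present in some libraries only and for the line B segments.

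The rule for named genes, fixed before the data were examined, took Stat5a, Stat5b, Stat3 and the milk protein genes, then the 10 largest positive and 10 largest negative changes past the threshold with a mean of 5 or more in the higher group and no overlap of libraries, then list members. Segments without a name are given by position, and only some of those the rule took are described. Gene lists were tested with limma's camera (inter-gene correlation 0.01) where 4 or more members had been placed, which held for 6 of 26 lists. The same steps from log2 values on were tested on simulated data for line C against WT, with 200 of 17264 segments changed. Of 50 segments changed by 1 on the log2 scale 6% were called, of 50 changed by 2, 82%, and of those changed by 3 or 4, 98%, with 5 unchanged segments called. In the data 40.3% of segments were called in line C against WT, which makes the adjustment less strict. These shares therefore hold for a comparison with few changes and not for line C as measured. After the data were seen, line B values were also drawn 50 times around the WT means with each segment's fitted SD, to see what share of segments called in either line would differ between the lines with line B unchanged.

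Alternatives were other scalings, pseudocounts, filters, variance settings, leaving out each library, a replicate block and a fold change threshold, all fixed before the data were examined. Other segment gaps, 10 kb bins, longer segments, removal of a regional trend and a crossed block were added after seeing the data.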

Results

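RNA-seq signal along the mouse genome was measured in mammary gland taken on lactation day 1, when the secretory epithelium makes milk. The study concerned an enhancer of the Stat5 locus, which encodes the transcription factors STAT5A and STAT5B that act downstream of prolactin. There were 6 libraries in 3 groups of 2: wild type (WT), line B and line C, which carry mutations of GAS elements, the DNA sites that STAT proteins bind, at a putative Stat5 enhancer. Line C carries mutations of both elements. The sample labels assign the single mutation of line B to the first element and the series description to the second, so line B is called here only the line with 1 mutated element. WT animals were C57BL/6 and both lines were of mixed C57BL/6J x CBA/J background, so strain could not be separated from genotype in a comparison with WT. The ChIP-seq samples of the series were not analysed here.

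The files gave coverage, from which the number of reads was estimated at 32.1 and 31.7 M (M, 1000000 reads) in WT, 35.4 and 32.3 M in line B, and 15.5 and 15 M in line C. Each read had been extended to a fixed length that differed between libraries, from 367 bp in line B replicate 2 to 929 bp in line C replicate 2. Of the files, 4 lacked long stretches of chromosomes 1 to 6 and 19, 798.7 Mb in WT replicate 1 and 173.0 Mb in line B replicate 2, and both line C files lacked none. Comparisons used the 1666.6 Mb, or 63.1% of the positions spanned, that all 6 files covered. On these positions 17264 transcribed segments were tested. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries.

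Libraries of WT and line B correlated with one another at Pearson r between 0.892 and 0.935 across segments, which are not independent replicates. The line C libraries correlated with each other at 0.928 and with the other libraries at 0.577 to 0.678. The 20 segments with the most signal took 45.3% and 47.5% of segment signal in WT, 39.1% and 41.7% in line B, and 15.8% and 29.6% in line C. Mitochondrial signal was 4.88% and 3.80% in WT, 3.03% and 3.74% in line B, and 0.79% and 0.43% in line C.

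The first question was how the mutations relate to transcription of the Stat5 genes themselves. Gene names here and below are provisional: no annotation of the files' build (mm9) was used, and loci were placed from general knowledge of the mouse genome, with the order of neighbouring genes taken from a table of another assembly (GRCm38.p6). Signal placed at Stat5a (chromosome 11, 100720745 to 100747250) was 20.5 ± 0.949 (SD, n = 2) in WT, 7.69 ± 2.21 in line B and 3.52 ± 0.773 in line C, in scaled signal per kb. Signal placed at Stat5b (chromosome 11, 100641567 to 100711768) was 7.87 ± 0.0374 in WT, 4.08 ± 0.298 in line B and 2.56 ± 0.434 in line C. In line C, Stat5a fell by 2.47 on the log2 scale (SE 0.25, limma, Benjamini-Hochberg adjusted p = 0.00063) and Stat5b fell by 1.54 (SE 0.20, limma adjusted p = 0.0015). Without either WT or either line C library, and under every scaling tried, both calls in line C were kept. In line B the log2 differences from WT were -1.41 for Stat5a (SE 0.25) and -0.91 for Stat5b (SE 0.20). Both line B libraries lay below both WT libraries for each gene, but limma's adjusted p over all segments was 0.31 and 0.62, and lay between 0.18 and 1 for Stat5a under the alternatives. Adjusted over the list alone, which held 3 placed genes, limma's adjusted p was 0.0023 for Stat5a and 0.0037 for Stat5b. Unadjusted, limma's p was 0.00078 for Stat5a and 0.0024 for Stat5b. The adjustment over all segments is stricter where few segments are called. That number was 23 in line B against WT and 7252 in line C against line B. Adjusted p therefore cannot be compared between these comparisons.

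**Figure D1:**
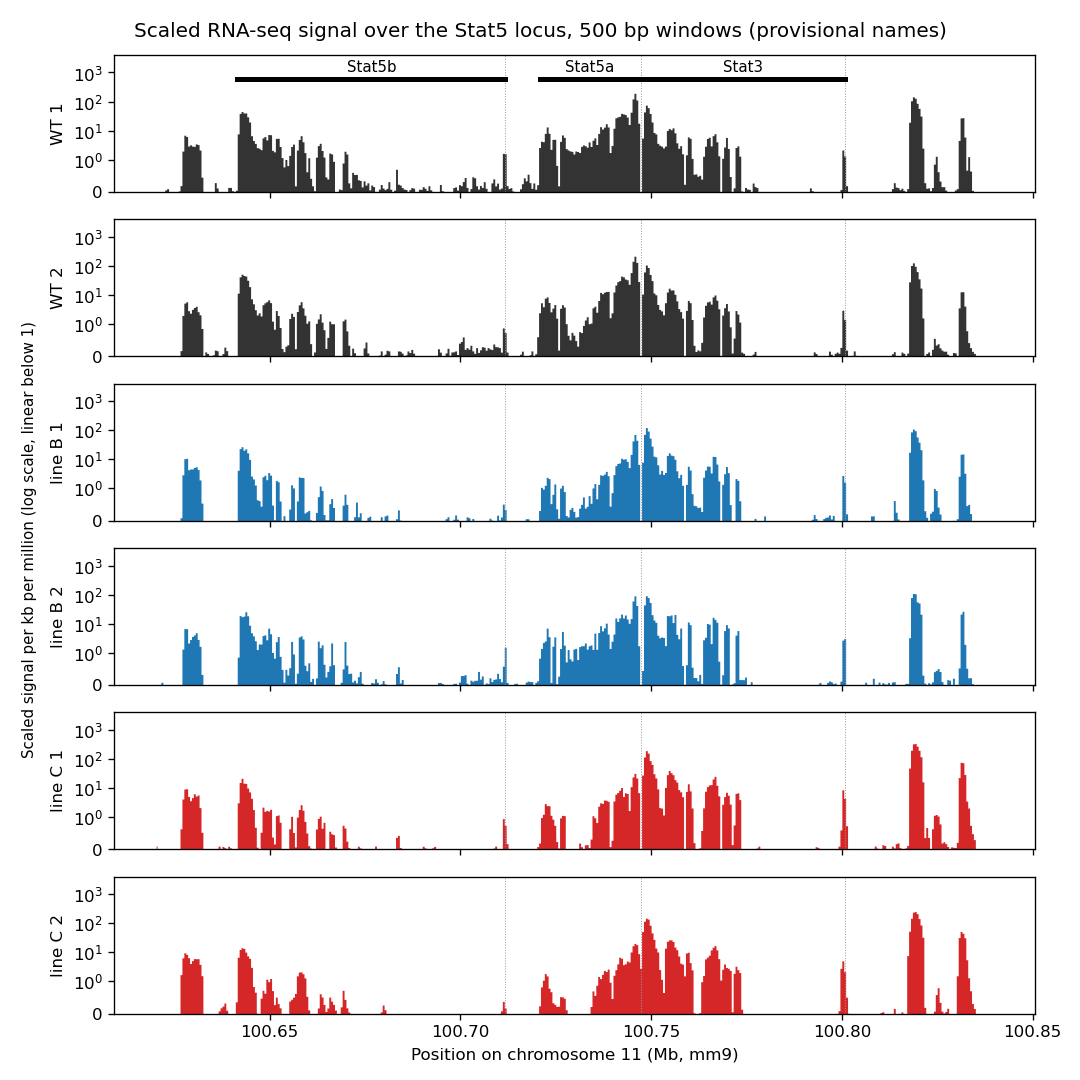
Scaled signal per kb (log axis, linear below 1) in 500 bp windows along chromosome 11 (Mb, mm9), 1 panel per library, with black bars for the loci provisionally named Stat5b, Stat5a and Stat3. Mean signal over Stat5a was 20.5 in WT, 7.69 in line B and 3.52 in line C.

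Line C was also compared directly with line B, which shares its strain label. That label is of a mixed background and does not state the haplotype of each locus: signal placed at H2-Ea, a histocompatibility gene that C57BL/6 mice are known not to express, was 8.01 and 15.2 in line C and at most 0.0149 in line B, and was 9.6 in WT replicate 1 and listed at 0 in WT replicate 2. Stat5a was lower in line C by a log2 difference of -1.06 (SE 0.25, limma adjusted p = 0.014) and Stat5b by -0.63 (SE 0.20, limma adjusted p = 0.039). These calls depended on the scaling: with scaling to total signal alone the log2 differences were -0.70 (limma adjusted p = 0.11) and -0.28 (limma adjusted p = 0.46). Over all alternatives limma's adjusted p lay between 0.0095 and 0.15 for Stat5a and between 0.018 and 0.6 for Stat5b. The Stat5a call was also lost without line B replicate 2 (-0.77) or line C replicate 2 (-0.85). The Stat5b call was lost without any 1 library except line C replicate 1. It was -0.70 without line B replicate 1, -0.56 without line B replicate 2 and -0.47 without line C replicate 2. Without either WT library the Stat5b difference stayed at -0.63, and the call was lost through a spread estimated from fewer libraries. Signal placed at Stat3, the neighbouring gene on chromosome 11 (100747251 to 100800767), was 10 ± 2.18 in WT, 11.8 ± 0.442 in line B and 21.1 ± 2.25 in line C (SD, n = 2). Stat3 was higher in line C than in WT by 1.07 on the log2 scale (SE 0.20, limma adjusted p = 0.0069), a call lost without WT replicate 1 (0.85, limma adjusted p = 0.055). Stat3 was higher in line C than in line B by 0.82 (SE 0.20, limma adjusted p = 0.018), a call lost without line B replicate 1 (limma adjusted p = 0.062), line B replicate 2 (limma adjusted p = 0.082) or line C replicate 1 (limma adjusted p = 0.059). Stat5a and Stat3 signal was not split by strand and was parted in the lowest window between them (100747001 to 100747500). That window was listed at 0 in WT replicate 1 and both line B libraries and was 0.0246 in WT replicate 2, and 0.0255 and 2.8 in line C.

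Milk protein loci came next, as STAT5 is known to act on them. Of 4 placed milk protein loci tested, 3 were lower in line C than in WT and 1 did not pass, and 3 passed when adjusted over the list alone. Markers of other cell types differed in line C as well, and 3 of 3 placed adipocyte loci were higher than in WT by limma. Of 4 placed fibroblast and matrix loci 3 were higher and 1 was lower, of 2 placed macrophage and granulocyte loci 1 was higher, and 3 placed basal keratin loci did not pass, though each passed with total signal alone (limma adjusted p of 0.0041 to 0.04, and 0.0036 to 0.99 over all alternatives). In the list for luminal hormone-sensing epithelium, 2 of 2 placed loci, both keratins of luminal cells, were higher. The luminal lineage also holds the milk-secreting cells. With the reported scaling the counts were the same adjusted over each list alone. Cidec, a lipid droplet protein, was 32.3 ± 17.4 in WT and 182 ± 126 in line C, Krt18, a luminal keratin, was 80.8 ± 17 and 301 ± 13.9, and Col6a1, a collagen chain, was 5.07 ± 0.0101 and 12.8 ± 4.96 (SD, n = 2). These limma calls were lost without WT replicate 2 for Cidec (limma adjusted p = 0.08), without WT replicate 1 for Krt18 (limma adjusted p = 0.052) and without either WT library for Col6a1 (limma adjusted p = 0.057 and 0.061). Xdh, xanthine dehydrogenase of the milk fat globule (chromosome 17, 74223769 to 74293808), was 77.3 ± 14.5 in WT, 66.9 ± 2.55 in line B and 18.2 ± 9.56 in line C (SD, n = 2), and fell by 2.16 on the log2 scale in line C (SE 0.36, limma adjusted p = 0.0042). Btn1a1, butyrophilin of the same globule (chromosome 13, 23547744 to 23558312), was 795 ± 218 in WT, 678 ± 6.34 in line B and 236 ± 115 in line C. Its log2 difference in line C was -1.81 (SE 0.56, limma adjusted p = 0.039), and the call was lost without any 1 library except line C replicate 2. Without WT replicate 1 the difference was -2.1, without WT replicate 2 -1.53 and without line C replicate 1 -1.29. Without either line B library it stayed at -1.81, and the call was lost through a spread estimated from fewer libraries. Lpo, lactoperoxidase (chromosome 11, 87619302 to 87642233), differed by -1.91 in line C (SE 0.58, limma adjusted p = 0.036). The call was lost without WT replicate 1 (-1.71) or WT replicate 2 (-2.11). It was also lost without either line B library. Line B does not enter this difference, which stayed at -1.91, so that loss came through a spread estimated from fewer libraries. Lalba, alpha-lactalbumin (chromosome 15, 98310010 to 98313893), was 3910 and 4800 in WT, 5300 and 2930 in line B, and 442 and 1720 in line C. Its log2 difference in line C, -2.31 (SE 1.34), did not pass (limma adjusted p = 0.20). It passed with all libraries when the variance trend was left out or a robust fit was used (limma adjusted p = 0.033 and 0.034) and without line C replicate 2 (-3.29, limma adjusted p = 0.029), and over the alternatives limma's adjusted p lay between 0.029 and 0.58. None of these 4 passed in line B, where their log2 differences were -0.20, -0.20, 0.04 and -0.14 and each turned sign under some alternatives.

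**Figure D2:**
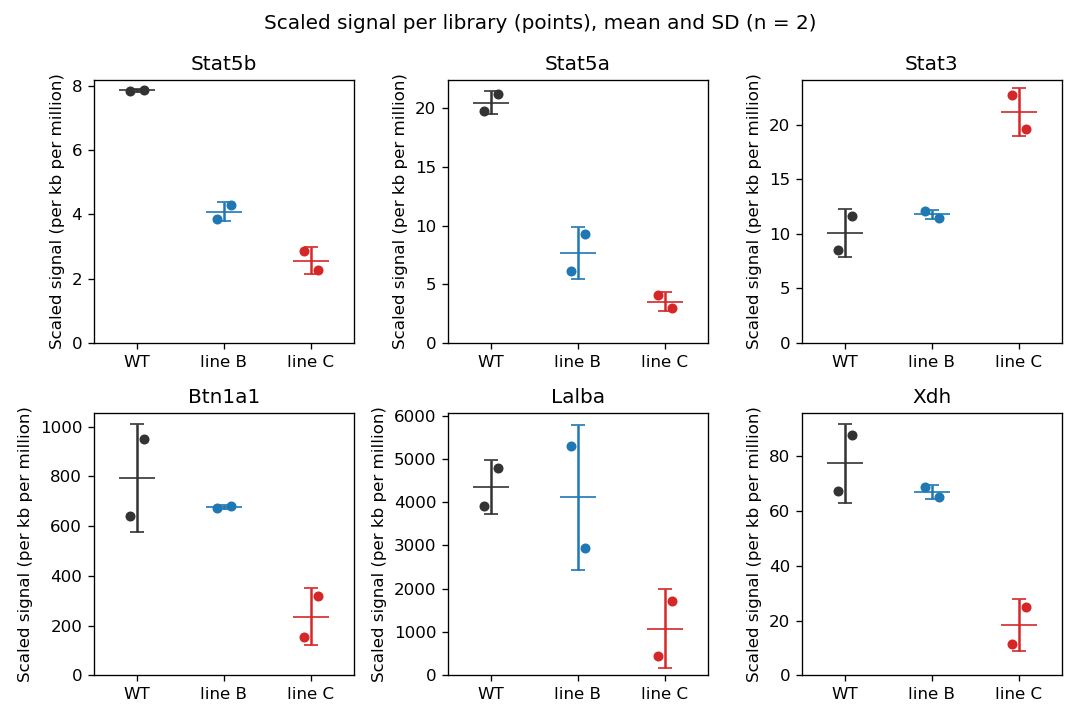
Scaled signal per kb (linear axis from 0) at 6 provisionally named loci, with a point per library and the mean and SD of the 2 libraries of each group. Stat5b and Stat5a were lowest in line C, and Xdh was 77.3 in WT, 66.9 in line B and 18.2 in line C.

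The casein genes on chromosome 5 lie where several files lack data, so they were left out of the test and each library that held a window in full is given. In the window placed at Csn3, kappa-casein (88350001 to 88365000), signal was 5880 and 6310 in WT, 5690 in line B replicate 1, and 18.8 and 106 in line C. In the window placed at Csn1s2b (88232001 to 88258000) it was 286 and 181 in WT, 155 in line B replicate 1, and 0.0361 and 0.322 in line C. In the window placed at Csn1s2a (88198001 to 88222000) it was 15700 in WT replicate 1, 15400 in line B replicate 1, and 456 and 2970 in line C. In the window placed at Csn2, beta-casein (88118001 to 88131000), which only the line C files held in full, it was 1220 and 5190. In the window placed at Csn1s1 (88090001 to 88115000) it was 11000 in line B replicate 2 and 178 and 1140 in line C. At every one of these windows line C replicate 1 was lower than line C replicate 2.

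Across all segments, line C differed from WT at 6959 of 17264 segments, 40.3%, with 2598 higher and 4361 lower (limma, Benjamini-Hochberg adjusted p below 0.05). The direction depended on the scaling: 37.3% of called segments were higher in line C with median-of-ratios scaling, 65.6% with total signal alone, 69.6% with values as deposited and 48.5% with quantile normalization. Total signal alone moved the median log2 difference of all segments from -0.08 to 0.43 here, from 0.04 to 0.23 in line B against WT, and from -0.16 to 0.18 in line C against line B. Without WT replicate 1 there were 4253 calls, and without WT replicate 2 there were 3916, of which 25.4% were higher. The segment most reduced in line C under the naming rule lay on chromosome 10 (8267928 to 8270069), at 500 and 380 in WT and 0.0321 and 0.234 in line C. It was also low in line B, at 0.372 and 0.69. The segment most raised lay on chromosome X (11261060 to 11262011), at 0.0583 in WT replicate 1, listed at 0 in WT replicate 2 and both line B libraries, and at 49.8 and 28.7 in line C. It was little longer than 1 extended read of line C replicate 2 (929 bp), so reads stacked at 1 position could not be told from a transcript.

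Line B differed from WT at 23 of 17264 segments, 3 higher and 20 lower (limma, Benjamini-Hochberg). An unadjusted limma p below 0.05 was found at 521 segments. This is less than a share of 0.05 of all segments, the share expected if none differed, so the count is no excess. Without line B replicate 1 there were 14 calls. Of the 20 lower segments, 16 had signal under 1 in all 4 libraries of both lines. The median length of the 20 was 1302 bp against 2604.5 bp for all tested segments. Some of the 20 were as long as 1 extended WT read, 578 bp in replicate 1 and 663 bp in replicate 2. Examples lay on chromosome 7 (123578758 to 123579335) and chromosome 16 (75888249 to 75888911). There, reads stacked at 1 position could not be told from a transcript. Among the 20, longer segments on chromosome 12 (19252098 to 19254451) and chromosome 8 (122415844 to 122417292) had 207 and 171, and 120 and 112, in WT, and at most 0.177 in the lines. A segment on chromosome 14 (55153797 to 55156956) had its highest values in line B, at 17.7 and 21.6, against 0.249 and 0.0565 in WT, and was listed at 0 in both line C libraries. Its log2 difference was 5.66 from WT (SE 0.34, limma adjusted p = 0.0012) and that of line C from line B was -6.31 (limma adjusted p = 0.00014).

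Of the segments called in line B, 21 were called in the same direction in line C. Independent lists of these sizes would share 0.5 higher and 5.1 lower segments, and simulated unchanged groups against the shared WT libraries shared 0.1 on average. That simulation left both lines unchanged, so a small overlap was fixed by its design. It gives no expectation for data with 6959 calls in line C. The WT libraries were too few to split, so part of the excess over independent lists can come from sharing them. The covariance of the fold changes of both lines was 0.097, against 0.065 in the simulation, and their correlation was 0.18, against 0.50. The simulated correlation is that of lines both unchanged, so it cannot be set against the observed one, where line C changed widely. Line C and line B differed directly at 7252 segments, 2595 higher and 4657 lower in line C, and at 4765 without line B replicate 2. The percentage higher was 35.8% here, 53.7% with total signal alone, 59.0% with values as deposited and 49.3% with quantile normalization. Of 6961 segments called in either line against WT, 6199, or 89.1%, also differed between the lines by limma. With line B simulated as unchanged from WT the share was 91.7% on average. The simulated line B was drawn around the measured WT means and shares their error, which tends to raise its share.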

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

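The simulated share and the tests of the neighbours of the Stat5 genes, the rarer direction, the density trend and longer segments were chosen after the data were seen, and gene names are provisional. Results are given here where limma's test of line C minus line B found the effects of the lines to differ. This held for 6199 of 6961 segments called in either line, 89.1%, nearly all of them called in line C. With line B simulated as unchanged from WT the share was 91.7% on average (90.7% to 92.4% over 50 sets), so a high share arises from the calls of line C alone. The observed share lay below every simulated set, but line B was drawn around the measured WT means. The simulated line B thus shares the sampling error of the WT libraries, which tends to raise the simulated share. The shortfall therefore does not show that line B departed from WT. The simulated sets also called more segments in either line, 7504.6 on average against 6961. The cause of the lower share was not tested, nor how far the shared error accounts for it.

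Among placed genes, the log2 difference of line C minus line B was -1.06 for Stat5a, -0.63 for Stat5b and 0.82 for Stat3. Of 3 placed fat cell genes 3 were higher, with 2.63 for Cidec, 2.33 for Plin1 and 2.25 for Retn. Of 4 placed matrix and fibroblast genes 3 were higher and 1 was lower, with 2.36 for Col1a1, 1.52 for Col6a1, 1.75 for Thy1 and -1.77 for Lum. The luminal keratins differed by 1.63 for Krt18 and 1.38 for Krt8, and the basal keratins by 0.99 for Krt5, 1.19 for Krt14 and 0.92 for Krt17. Against WT the basal keratins Krt5, Krt14 and Krt17 were at -0.73, -0.61 and -0.75 in line B, where 3 of 3 passed adjusted over the list alone but did not pass over all segments (limma adjusted p = 0.77, 1 and 1), and at 0.26, 0.58 and 0.17 in line C, which did not pass either way. Of 5 placed milk lipid genes 2 were lower, with -3.44 for Scd2 and -2.25 for Acly, and 3 did not pass. Of 4 placed milk protein genes 2 were lower, with -1.96 for Xdh and -1.95 for Lpo, and 2 did not pass, of which 1 passed adjusted over the list alone. The others were 2.55 for Cd14, 1.86 for Socs3, 1.62 for Egr1, 1.10 for Dusp1, 1.63 for Aqp5, 0.91 for Birc5, -2.13 for Rrm2, -1.40 for Pim1 and 5.46 for H2-Ea. Of these 28 genes, 8 kept their limma call without each library in turn: Col6a1, Lum, Acly, Krt5, Xdh, Egr1, Cd14 and Scd2. Without line B replicate 1, 14 lost it (limma adjusted p of 0.05 to 0.16), and without line B replicate 2, 14 did (0.058 to 0.14). Without line C replicate 2, 8 lost it (0.051 to 0.14), without line C replicate 1, 4 did (0.052 to 0.09), and without either WT library only Stat5b did.

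The breadth of the line C difference may be technical in part, since line C has fewer reads and longer extension than the other groups. Its mitochondrial share was also lower, and whether that is technical was not tested. Removing each library's trend on local segment density, a rough stand-in for regional base composition, left 7324 calls against 6959, but moved the percentage higher from 37.3% to 48.1%, and from 35.8% to 48.3% against line B. As a rough stand-in, this trend cannot exclude a bias from base composition. Strong segments could set a library's factor wrong and move all segments 1 way. At least 2199 segments were called in the rarer direction under each scaling by 1 factor per library, so a wrong factor is not the whole cause. Among segments of 5 kb or more, where extension past the edges matters less, 54.6% were called against 40.3%. Longer segments can be called more easily in any case, so this does not tell how much extension adds. Base composition of the transcripts could not be computed without sequence, and depth followed line C. These and extension stay open beside the mutations. So do a changed cell makeup and strain haplotypes, which may differ between the lines as well (H2-Ea was 8.01 and 15.2 in line C and at most 0.0149 in line B).

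Lower Stat5a and Stat5b signal in both lines may reflect the mutated elements or the mixed strain background, and the line B difference did not pass limma's test over all segments. Other segments within 1 Mb had a median log2 difference of -0.06 between line B and WT (SD 0.29 over 56 segments), which argues against a shift of the whole region in line B. This was not examined in line C, where the neighbouring Stat3 was higher than in WT by 1.07. A strain difference at the Stat5 genes themselves, and the protocol text that differs between WT and the lines, stay open. So does a changed cell makeup in line C.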

How the results depend on the processing

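Segment gaps, 10 kb bins, longer segments, the density trend and the crossed block were chosen after seeing the data. No called locus of the naming rule and none of the 3 Stat loci changed direction under any alternative run; over these, 322 values under an alternative kept their side of the threshold and 2 lost a call in line B against WT, 927 and 66 in line C against WT, and 980 and 73 in line C against line B. Of 16 results given in the text though not called, 8 changed direction, in 23 of 349 values, and the cause was not tested. In line C against WT, Fasn was 0.12 with total signal alone, 0.17 as deposited and -1.35 to 0.42 without 1 library, Krt17 was -0.04 to 0.39 and Socs3 -0.03 to 1.46 without 1 library. In line C against line B, Cish was 0.13 with total signal alone, 0.19 as deposited, 0.02 with the density trend removed and -0.69 to 0.21 without 1 library. In line B against WT, Xdh was 0.01 with total signal alone and 0 with quantile normalization. Btn1a1 was 0.01 and 0.22 under these, and -0.49 to 0.08 without 1 library. Lpo was -0.03 with the density trend removed and -0.16 to 0.24 without 1 library. Lalba was 0.07 with total signal alone, 0.05 as deposited, 0 with quantile normalization and -0.56 to 0.29 without 1 library. In line C against WT, Lalba, Krt5, Krt14, Krt17, Socs3 and Akt1 passed in 13 values. Counts of called segments stayed within 1.5 times of the reported ones under the scalings, pseudocounts, variance settings and segment gaps run. With a mean scaled signal of 2 or more, fewer segments were tested, and counts were 4417 for line C against WT, 14 for line B against WT and 4475 for line C against line B. Among segments of 5 kb or more they were 2886, 1 and 2958, and with 10 kb bins line B against WT had 11. Leaving out 1 library gave 3916 to 6665 calls for line C against WT, 14 to 25 for line B against WT and 4765 to 6344 for line C against line B. A group left with 1 library was assumed to vary like the others. Leaving out a library of a group outside a comparison left its log2 differences unchanged and acted only through the estimated spread. Of 18 list tests 1 was called, 0 with an estimated correlation, 0 with fry, 3 with total signal alone and 0 to 4 without 1 library; the cause was not tested.

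The replicate numbers do not show that libraries were paired: deviations of same-numbered libraries correlated at -0.18 between WT and line B, 0.14 between WT and line C and -0.14 between the lines. With a replicate block there were 6238, 19 and 6540 calls and 1 list call, and with the numbers of line B crossed in the block 7924, 25 and 8130. Keeping bases shared between genes and using only the last exon bases were not run, since both need an annotation. Depth limits weak segments, most in line C.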

Other observations

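The presence pattern, and the test on it, were chosen after the data were seen. The gene lists and their tests had been planned, but the names were placed afterwards, and a wrong name would change these results. Among placed genes, 3 of 3 adipocyte genes were higher in line C than in WT by limma. Cidec, a lipid droplet protein, was 32.3 ± 17.4 in WT, 25.4 ± 1.06 in line B and 182 ± 126 in line C (SD, n = 2). Plin1, which coats lipid droplets, was 13.9 ± 6.83, 11.4 ± 2.84 and 60.9 ± 30.2. Without WT replicate 2 the calls of Cidec, Plin1 and Retn were lost (1.82, 1.59 and 1.66 on the log2 scale, limma adjusted p = 0.08, 0.056 and 0.077). Of 5 placed milk lipid genes 2 were lower in line C. Scd2, a fatty acid desaturase, fell by 3.93 on the log2 scale (SE 0.44, limma adjusted p = 0.00091) and Acly, which makes acetyl-CoA in the cytosol, fell by 2.22 (SE 0.39, limma adjusted p = 0.0048). Fasn, fatty acid synthase, was 415 and 206 in WT and 391 and 115 in line C, which did not pass.

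Krt8 and Krt18, keratins of luminal cells, were higher in line C than in WT by 1.48 and 1.91, calls lost without WT replicate 1 (limma adjusted p = 0.055 and 0.052). The basal keratins Krt5, Krt14 and Krt17 differed by 0.26, 0.58 and 0.17, which did not pass, but passed with total signal alone (0.84, 1.16 and 0.74, limma adjusted p = 0.017, 0.0041 and 0.04; 0.0036 to 0.99 over all alternatives). Of 4 placed STAT5 pathway genes 2 were lower in line C than in WT, Cish and Pim1, and 2 did not pass, with 3 past the threshold adjusted over the list alone. Cish, a known STAT5 target, was 43.6 ± 17.1 in WT, 14.4 ± 1.65 in line B and 12.7 ± 5.52 in line C (SD, n = 2). Its log2 difference was -1.53 in line B (limma adjusted p = 0.82; 1 of the 4 passed adjusted over the list alone) and -1.77 in line C (limma adjusted p = 0.0095), a call lost without WT replicate 2 (-1.36, limma adjusted p = 0.054). Line C minus line B was -0.24 for Cish, which did not pass (limma adjusted p = 0.63). The adjustment is stricter in line B against WT, where few segments were called, so the adjusted p of Cish cannot be compared between the lines. Pim1, a kinase, differed by -1.22 in line C (limma adjusted p = 0.016), a call lost with total signal alone (-0.64, limma adjusted p = 0.065), as deposited (limma adjusted p = 0.085), without WT replicate 2 (limma adjusted p = 0.098) and without line C replicate 1 (limma adjusted p = 0.057; 0.0029 to 0.098 over all alternatives). The genes that did not pass were Socs3 at 0.72 (limma adjusted p = 0.27), which passed without WT replicate 2 (1.46, limma adjusted p = 0.04; 0.04 to 0.96 over all alternatives), and Akt1 at -0.74 (limma adjusted p = 0.077), which passed without line C replicate 2 (-1.14, limma adjusted p = 0.0077; 0.0077 to 0.71) and with quantile normalization (limma adjusted p = 0.038).

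Few list members were placed, and 20 of 26 lists were not tested. Camera called 1 of 18 tests, the immediate early genes in line B against WT (median log2 difference -0.57, 4 members, limma camera adjusted p = 0.046; adjusted p = 0.66 with an estimated correlation). The other camera tests had adjusted p of 0.092 to 0.82. In line C against WT it was 0.12 for milk proteins, 0.36 for the STAT5 pathway, 0.21 for milk lipid synthesis, 0.26 for fibroblast and matrix genes, 0.12 for involution and acute phase and 0.22 for immediate early genes.

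At 5 segments signal was 5 or more in WT replicate 1 and both line C libraries and 0.5 or less in WT replicate 2 and both line B libraries. Of the 20 ways to choose 3 of the 6 libraries, the next highest gave 1 such segment. Of these 5, 4 lie on chromosome 17 between 34478624 and 36305993, and 1 is provisionally H2-Ea, a class II histocompatibility gene that C57BL/6 mice are known not to express. It was 9.6 in WT replicate 1, 8.01 and 15.2 in line C and at most 0.0149 in the other libraries. A hypothesis is that WT replicate 1 may carry another haplotype there than WT replicate 2, which would go against its strain label, and line C another than line B, which their label of a mixed background allows. A mixed or mislabelled sample was not told apart from a mixed background.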
